A study of Mus musculus with 17 samples.

How the data were processed

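Hepatocytes came from 3-month-old C57BL/6J mice of the ApcΔHep genotype that had carried AAV8 with SaCas9 constructs for 1 month and received tamoxifen (2 mg, 7 days), per the labels' protocols. RNA was extracted with Trizol, per the labels. RNA-seq covered 6 libraries edited at the WRE and 5 edited at Rosa26, and miRNA-seq covered 3 and 3.

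RNA-seq values were expected counts per Ensembl gene, 1 deposited table per library, made with STAR 2.7.6a and RSEM 1.3.1 on GRCm38, per the submitters' processing notes and the file headers. The strand setting and annotation version are not given in the sources used here. The same deposited tables hold other values, the effective length of each gene in bases, per the file headers. A deposited matrix of normalized signal from DESeq2 1.26.0 in R 3.6.3, per the submitters' processing notes, held 15322 genes. The ratio of expected counts to that signal varied by 11.7% to 19.4% between genes of a library, so the matrix was not made with 1 size factor per library, and it was used as a check alone (Spearman's rho 0.994 to 0.998 across genes with the log2 CPM used here). Deposited miRNA values were whole-number counts per mature miRNA, with identical mature sequences joined, and the aligner and counter of the miRNA reads are not given in the sources used here. The run of each RNA-seq library was read from the library name in the labels, and it matched the run in the deposited design table, a label of the other kind. Another deposited design table, for the miRNA libraries, repeats the conditions and was not used.

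Expected counts were rounded to whole numbers. Of 55536 gene identifiers, 55450 matched the gene name table, and coordinates came from a RefSeq table of GRCm38.p6, 1-based. B830012L14Rik had no coordinates there. RNA-seq totals were 20727036 to 38935135 expected counts and miRNA-seq totals 1393509 to 2011383 counts. Intervals on shares of counts were 95% exact binomial (Clopper-Pearson) intervals, and they cover counting error alone. Replicates of a group differed far beyond counting noise in every pair, so the tests rest on the spread between libraries.

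Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr by group with default settings (a minimum count of 10 and a minimum total of 15), TMM factors and a robust quasi-likelihood fit, two-sided. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The RNA-seq design held the run and the group, so the effect came from r770 and r595, while the 2 WRE-edited libraries of r711 added to the estimate of the spread alone. The residual degrees of freedom were 7. The miRNA-seq design held the group. Standard errors of log2 fold changes came from the quasi-likelihood statistic. After the filter 14393 of 55536 genes and 355 of 476 miRNAs were tested. CPM values are scaled with TMM factors.

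Gene lists were fixed before the data were examined. The RNA-seq lists were the DLK1/DIO3 locus, its flanks, β-catenin and pericentral genes, periportal genes, cell cycle, hepatocyte identity, oncofetal genes, imprinted genes elsewhere, lipogenesis, cholesterol synthesis, PPARα and fatty acid oxidation, bile acids, xenobiotics, acute phase, interferon, p53 and DNA damage, endoplasmic reticulum stress, early genes of dissociation, thyroid hormone response, and markers of cholangiocytes, stellate cells and fibroblasts, endothelium, macrophages, neutrophils, lymphocytes and erythroid cells. The miRNA lists were the locus, liver, miR-17-92, p53, miR-200, blood cell, and mesenchymal and endothelial miRNAs. Each of the 26 RNA-seq lists was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. With the preset correlation 7 lists passed, with an estimated correlation 0, and with fry 2, the locus and cell cycle. Counts adjusted over the list alone used the same p-values with the adjustment over the members of 1 list.

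The genes named were chosen by a rule written before the data were examined. It took every measured locus gene, up to 10 genes in each direction past the threshold with the same sign in r770 and r595, up to 4 members of each other list by smallest p, Glul, Axin2, Lgr5 and Cyp2e1 in any case, and for miRNAs the 10 locus miRNAs with the smallest p and up to 5 in each direction outside the locus past the threshold. miRNAs named outside the locus were the list members with the smallest p, chosen after their values were seen. Some genes that the rule takes are not reported here.

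The methods were tested on simulated data with known changes. In the RNA-seq design over 14393 genes, the fit recovered 8.96% of genes changed 1.41-fold, 59.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 4 false calls. In the miRNA-seq design over 355 miRNAs it recovered 40% of those changed 2-fold and 90% of those changed 4-fold, with 2 false calls. Of 26 simulated lists the 1 lowered list was called and 0 others. The simulated counts were drawn independently for each gene, with the spread taken from its trend over expression and with no run effect. These rates therefore do not carry over to real genes with their own spread, or to lists whose genes move together.

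Alternatives were DESeq2 size factors, DESeq2 1.42.0 Wald tests, no filter, a stricter filter (50 counts in at least 5 libraries), no run term, run r770 alone, no r711 libraries, summing WRE-edited 4 and 6, whose names carry the same number (which may mark 1 animal, although another number names a WRE-edited library in miRNA-seq and a Rosa26-edited library in RNA-seq), a replicate block, leaving out each library, and for miRNAs also factors computed without the locus and library totals. Added after seeing the data were effective lengths as offsets, leaving out mitochondrial and 7S RNA genes, leaving out WRE-edited 6 with Rosa26-edited 2 and 5, leaving out WRE-edited 3 and 6, and a score of non-hepatocyte markers as a covariate. Other splits of the libraries were limited to those that keep the number of each group within each run, of which there are 60, since the run is part of the design; miRNA-seq has 10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.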

Results

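Hepatocytes were isolated by collagenase perfusion from livers of ApcΔHep mice, whose hepatocytes lose Apc, the brake on β-catenin signalling. The mice received tamoxifen, a drug used to switch on inducible gene deletion, and AAV8, a viral vector that reaches hepatocytes, carrying constructs of SaCas9, a compact Cas9 nuclease. The constructs edited either the Rosa26 locus, a site widely used as a neutral control, or a β-catenin binding site upstream of the DLK1/DIO3 locus, which the labels call WRE. RNA-seq covered 6 WRE-edited and 5 Rosa26-edited libraries, and miRNA-seq covered 3 and 3. The RNA-seq libraries came from 3 runs: r770 held 3 WRE-edited and 3 Rosa26-edited libraries, r595 held 1 and 2, and r711 held 2 WRE-edited libraries and no control. RNA-seq totals were between 20727036 and 38935135 expected counts per library, and miRNA-seq totals were between 1393509 and 2011383 counts. Mitochondrial ribosomal RNA took 2.29% to 3.00% of the counts in the 3 r595 libraries and 19.02% to 29.09% in the other 8. The labels do not say whether the libraries come from separate animals, so the p-values measure the spread between these libraries. Fold changes are WRE-edited against Rosa26-edited, with the run as a term for RNA-seq. Group means of CPM include the 2 r711 libraries, while the RNA-seq fold changes rest on r770 and r595. A fold change can therefore differ from the ratio of the means. WRE-edited 6 is the only WRE-edited library of r595. Without it, fold changes fitted with the run term rest on r770 alone, since Rosa26-edited 4 and 5 drop out of the effect too.

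The first comparison asked what editing the WRE did to the transcripts of the DLK1/DIO3 locus, an imprinted domain of long non-coding RNAs, small RNAs and a few protein-coding genes. All 5 measured transcripts of the list fixed in advance were lower in the WRE-edited hepatocytes, by a median log2 fold change of -2.30 (4.94-fold). Gm34667, a measured gene between Mirg and Dio3 that was not on the list, had 1.32 ± 0.51 and did not pass (adjusted p = 0.441). Rian, a long non-coding RNA that hosts small nucleolar RNAs, fell from 283 ± 97.7 CPM (counts scaled to library size; SD, n = 5) to 74.4 ± 27.1 (SD, n = 6), a log2 fold change of -2.30 ± 0.26 (SE; edgeR adjusted p = 0.0188). Without the run term the log2 fold change of Rian was -1.93. Meg3, the long non-coding RNA at the start of the cluster, was at 52.7 ± 15.7 CPM (SD, n = 6) against 238 ± 168.03 (SD, n = 5), a log2 fold change of -2.23 ± 0.45. Mirg, which hosts many of the microRNAs, was at 8.72 ± 4.20 CPM against 35.6 ± 16.7, a log2 fold change of -2.27 ± 0.47. Rtl1, a gene derived from a retrotransposon, was at 3.71 ± 1.61 CPM against 16.4 ± 8.99, a log2 fold change of -2.46 ± 0.44. The non-coding transcript B830012L14Rik was at 0.561 ± 0.391 CPM against 3.29 ± 3.57, a log2 fold change of -2.66 ± 0.75.

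Over all 14393 genes tested, Rian alone passed, with adjusted p = 0.213 for Rtl1, 0.266 for Meg3, 0.281 for Mirg and 0.384 for B830012L14Rik in edgeR. Adjusted over the list alone, all 5 were lower, with adjusted p from 6.51e-06 for Rian to 0.00408 for B830012L14Rik, and DESeq2 called all 5 over all genes. As a set the locus was lower with the preset correlation of camera (adjusted p = 4.28e-09) and with fry (adjusted p = 0.0192), and had adjusted p = 0.180 with an estimated correlation. Within run r770 the log2 differences were -2.25 for Rian, -1.87 for Meg3, -2.21 for Mirg, -1.96 for Rtl1 and -1.47 for B830012L14Rik, and within r595 they were -2.28, -2.36, -2.58, -3.13 and -3.98. Every WRE-edited library lay below every Rosa26-edited library for Rian, Mirg and Rtl1. For Meg3, WRE-edited 4 at 83.9 CPM was above Rosa26-edited 2 at 79.8 CPM. The groups overlapped more for B830012L14Rik. There WRE-edited 1, 4 and 5 (0.622, 0.904 and 1.13 CPM) were above Rosa26-edited 2 (0.366 CPM). WRE-edited 4 and 5 were also above Rosa26-edited 3 (0.892 CPM). The over-all-genes call of Rian was lost in 13 of 26 alternatives, among them without WRE-edited 2, 3, 4, 5 or 6 or Rosa26-edited 2 in turn (adjusted p 0.148, 0.165, 0.0528, 0.0535, 0.317 and 0.0669), at log2 fold changes from -2.22 to -2.37.

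**Figure D1:**
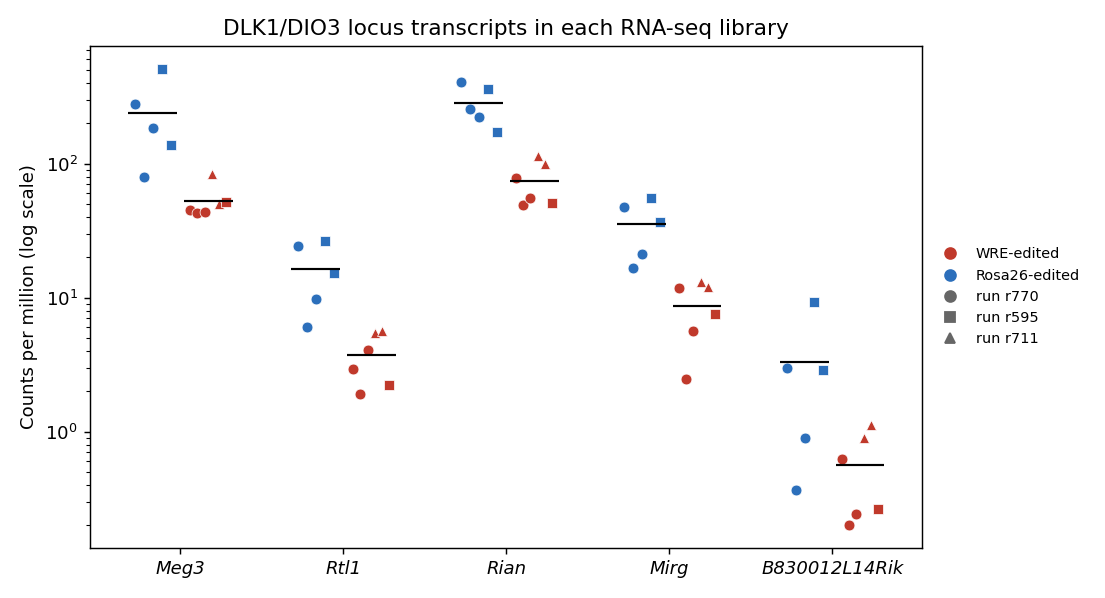
CPM (log scale) of the 5 measured DLK1/DIO3 locus transcripts, with 1 point per RNA-seq library, coloured by group and shaped by run, and the group mean. The 6 WRE-edited libraries lie below the 5 Rosa26-edited libraries for Rian, Mirg and Rtl1, and Rian averages 74.4 CPM against 283 CPM.

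Along chromosome 12 of GRCm38 the transcripts follow one another, with Meg3 at 109540996 to 109571729, Rtl1 at 109564900 to 109604418, Rian at 109603945 to 109661716 and Mirg at 109734981 to 109749458. Rtl1 overlaps the annotated ends of Meg3 and Rian, and the strand setting of the counting is not given in the sources used here, so reads in the shared stretches cannot be assigned with certainty. Dlk1 (109452485 to 109463336), which encodes a membrane protein of fetal liver, had 17 counts in all WRE-edited libraries together and 30 in all Rosa26-edited libraries, with at most 13 in any library (0.48 CPM). Dio3, the thyroid hormone inactivating deiodinase at 110279230 to 110281097, had 11 and 4 counts, and its antisense Dio3os had 28 and 19. These 3 genes were below the filter. Fitted without a filter they had -0.05, 1.15 and -0.04, at unadjusted p of 0.960, 0.415 and 0.965, and with so few counts this does not show that they stayed level. Outside the locus and within 2 Mb of it, 0 of 40 measured genes passed in edgeR. The single one at an unadjusted p under 0.05 was the transcription factor gene Yy1, at a log2 fold change of 0.39 ± 0.18, and the 40 ranged from -0.76 to 0.77. The flanking list of 16 measured genes fixed in advance had a median of 0.10 and adjusted p = 0.425, with 1 gene at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2.

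Over all 14393 genes tested, the locus included, edgeR called 0 genes higher and 1 lower, which was Rian. At an unadjusted p under 0.05 there were 713 higher and 740 lower genes, 1453 in all against the 720 that chance would give. DESeq2 called 17 higher and 66 lower, with the 5 locus transcripts among the lower ones. The excess over chance depended on the libraries kept and on the design. The number was 607 without WRE-edited 6, which takes the whole of r595 out of the effect and is more than the loss of 1 library. It was 795 without WRE-edited 3, while leaving out any other single library gave 1131 to 2167. It was 449 with r770 only, 635 without the run term, and 632 with WRE-edited 4 and 6 summed and no run term. With a replicate block it was 604 with the run term and 672 without it. It was 496 without WRE-edited 6 and Rosa26-edited 2 and 5, and 444 without WRE-edited 3 and 6. A difference of the effect between runs r770 and r595 was tested as an interaction in edgeR, which gave 0 of 14582 genes, with 951 at an unadjusted p under 0.05 against 729 by chance, and DESeq2 was not run for it. Since r595 held 1 WRE-edited library, the 0 does not show that the effect was alike in both runs.

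Genes of the cell cycle were lower in the WRE-edited libraries where a run held both groups. Of 28 measured members, 26 had negative fold changes, with a median of -0.75 (1.68-fold); the median difference was -0.65 within r770 and -1.12 within r595. Ccna2, the cyclin of S phase, had a log2 fold change of -1.31 ± 0.22 (SE), at 4.94 ± 2.86 CPM (SD, n = 6) against 8.20 ± 2.15 (SD, n = 5). Ccnb1, the cyclin of mitosis, had -1.40 ± 0.24. Its means were 5.74 ± 5.02 CPM (SD, n = 6) against 6.01 ± 2.43 (SD, n = 5), with 13.5 and 10.4 in WRE-edited 4 and 5 of r711. The mitotic kinesin Kif20a had -1.16 ± 0.22 and the topoisomerase Top2a -0.97 ± 0.18. Over all genes 0 passed in edgeR (adjusted p = 0.213 for each of these 4), 18 were lower at an unadjusted p under 0.05, DESeq2 called 7 lower, and 18 were lower adjusted over the list alone. The list was lower with the preset correlation (adjusted p = 6.68e-17) and with fry (adjusted p = 0.0192), and had adjusted p = 0.180 with an estimated correlation. The list's mean log2 CPM was 1.60 to 2.08 in the 3 WRE-edited libraries of r770 against 2.29 to 2.57, and 1.52 in WRE-edited 6 against 2.45 and 2.62. WRE-edited 4 and 5 of r711, a run with no control, had 2.48 and 2.77, and without the run term the median was -0.30 and 0 members passed adjusted over the list alone. WRE-edited 3 and 6, the lowest in cell cycle genes, also had the lowest stellate cell score (0.61 and 0.67), and without WRE-edited 6 the number adjusted over the list alone was 8. With effective lengths as offsets the median was -0.45 and the number 10, and with WRE-edited 4 and 6 summed and no run term they were -0.32 and 0.

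**Figure D2:**
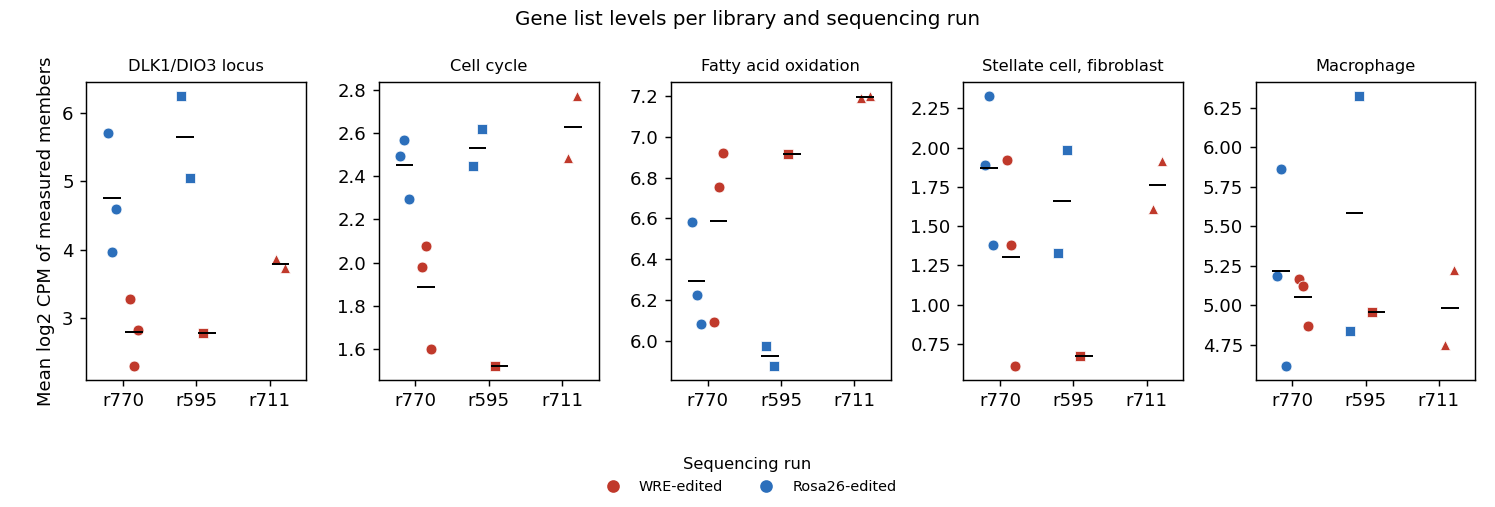
Mean log2 CPM of the measured members of 5 gene lists in each RNA-seq library, by run and group, with black lines at the mean of each group within a run. In r770 and r595 the WRE-edited libraries lie below the Rosa26-edited ones for the locus and for cell cycle genes, while the r711 libraries have no control and lie at 2.48 and 2.77 for cell cycle genes.

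Genes of fatty acid oxidation controlled by PPARα, the fatty acid sensing receptor, were higher in the WRE-edited libraries, with 17 of 19 members positive and a median log2 fold change of 0.36 (camera adjusted p = 3.18e-05). The list had adjusted p = 0.683 with an estimated correlation. With the preset correlation, 39 of the 60 splits within runs gave at least as many lists as the real 7. A pass by this test alone therefore does not set this list, or those below, apart from chance. In r770 the list's mean log2 CPM in WRE-edited 1 (6.09) lay below Rosa26-edited 1 and 2 (6.58 and 6.22). The ω-hydroxylase gene Cyp4a14 stood at 119 ± 56.0 CPM (SD, n = 6) against 16.8 ± 13.2 (SD, n = 5), a log2 fold change of 2.75 ± 0.77. WRE-edited 1 had 11.3 CPM, within the Rosa26-edited range. The dehydrogenase gene Acadl had 0.36 ± 0.14 and the thioesterase gene Acot2 0.42 ± 0.17. In edgeR 0 passed over all genes and 0 adjusted over the list alone, with 8 higher at an unadjusted p under 0.05 and 0 by DESeq2. The medians were 0.21 within r770 and 0.70 within r595, and the median was 0.06 (adjusted p = 0.655, in a range over alternatives from 6.32e-13) without WRE-edited 3 and 6.

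Hepatocyte identity genes had a median of 0.14 with 18 of 24 positive (camera adjusted p = 0.0148, and adjusted p = 0.683 with an estimated correlation). The liver transcription factors Foxa2 (0.80 ± 0.17) and Foxa3 (0.46 ± 0.10) were higher adjusted over the list alone (both adjusted p = 0.00733) and by DESeq2, while edgeR called 0 over all genes with 5 higher at an unadjusted p under 0.05. Over the list alone both were lost in 8 of 26 alternatives, including without WRE-edited 6. Hpd, which degrades tyrosine, had 0.51 ± 0.17 (0.33 without WRE-edited 6) and Cebpa, another liver transcription factor, 0.45 ± 0.17. The medians were 0.11 within r770 and 0.19 within r595. The call was lost in 5 of 25 alternatives: without WRE-edited 2 (median 0.12, adjusted p = 0.0665, in a range over alternatives from 0.00222 to 0.293), without the run term, with WRE-edited 4 and 6 summed, with a replicate block and no run term, and without WRE-edited 3 and 6.

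The question of β-catenin output was put to 21 measured pericentral and β-catenin target genes, which had a median of 0.20 and no call (camera adjusted p = 0.0582). The medians were 0.03 within r770 and 0.50 within r595, which held 1 WRE-edited library, WRE-edited 6. Glul, the glutamine synthetase gene that marks β-catenin activity in liver, was at 8588 ± 2862 CPM (SD, n = 6) against 7804 ± 971.0 (SD, n = 5), a log2 fold change of 0.28 ± 0.16. WRE-edited 6 was at 13954 CPM. Without that library, where the effect rests on r770 alone, Glul had 0.08. Its differences were 0.06 within r770 and 0.70 within r595. The feedback target Axin2 had 0.51 ± 0.27 (0.18 without WRE-edited 3, and -0.26 to 0.68 over alternatives), the receptor gene Lgr5 -0.12 ± 0.21 and the cytochrome gene Cyp2e1 0.26 ± 0.16 (0.07 without WRE-edited 6, 0.05 within r770 and 0.68 within r595). The transcription factor genes Tbx3 (0.86 ± 0.23) and Sp5 (0.72 ± 0.23, and 0.41 without WRE-edited 3) were the 2 at an unadjusted p under 0.05. The receptor genes Nr1i3 (0.50 ± 0.23) and Ahr (-0.26 ± 0.14) came next. In edgeR 0 passed over all genes, 0 passed adjusted over the list alone, and DESeq2 called 0. The list passed in 5 of 25 alternatives, without a filter and without WRE-edited 1 or 2 or Rosa26-edited 1 or 4 in turn (adjusted p 0.0358, 0.00291, 0.0179 and 0.0251).

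Other metabolic lists gave no call with camera over all libraries. Periportal genes had a median of -0.20 and passed lower in 1 of 25 alternatives, with Ass1 of the urea cycle at 0.50 ± 0.20, Otc at 0.20 ± 0.12, Hsd17b13 at -0.37 ± 0.23 and Arg1 at -0.60 ± 0.44 (-0.23 without WRE-edited 6 and -0.32 without Rosa26-edited 5). Cholesterol synthesis had a median of -0.17 (adjusted p = 0.129) and passed lower in 11 of 25 alternatives, with -0.16 within r770 but 0.16 within r595, and Insig1 (-0.63 ± 0.17) was lower adjusted over the list alone (adjusted p = 0.0331), which was lost in 12 of 26 alternatives, 7 of them without 1 library. In the same list Mvd had -0.51 ± 0.25 (-0.28 without WRE-edited 2). Thrsp, which promotes lipogenesis and responds to thyroid hormone, was at 45.9 ± 13.0 CPM against 80.1 ± 28.9, a log2 fold change of -1.03 ± 0.21, and was lower adjusted over either of its lists alone (adjusted p = 0.00564 for lipogenesis, 0.00263 for thyroid hormone response) and by DESeq2. These were lost in 4 and 3 of 26 alternatives. The rest of lipogenesis included Gpam (-0.27 ± 0.15), Srebf1 (-0.34 ± 0.20) and Fads2 (0.27 ± 0.18), with a list median of 0.03 against a mean of -0.04 and a downward test, which passed in 1 of 25 alternatives. Thyroid hormone response had a median of -0.01 and passed lower in 1 of 25 alternatives, with Hr at -1.08 ± 0.56 (-0.53 without Rosa26-edited 5), Thrb at -0.16 ± 0.16 and Dio1 at 0.32 ± 0.36. Bile acid genes had a median of 0.00, with Slco1b2 at -0.53 ± 0.19, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.61 ± 0.23, Slco1a1 at -0.44 ± 0.20 and Abcc3 at 0.29 ± 0.20. Xenobiotic genes had a median of 0.22 (adjusted p = 0.0699) and passed higher in 7 of 25 alternatives, 3 of them without 1 library (WRE-edited 2, Rosa26-edited 1 or Rosa26-edited 2). In this list Por had 0.65 ± 0.25, Cyp2b10 1.18 ± 0.53 (0.53 without WRE-edited 6), Ugt1a1 0.35 ± 0.16 and Cyp2c37 0.26 ± 0.13, the list medians were 0.00 within r770 and 0.68 within r595, and the differences of Cyp2b10 were 0.32 within r770 and 2.7 within r595.

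Among stress and growth lists, interferon response genes were lower, with 17 of 20 negative and a median of -0.25 (camera adjusted p = 0.00595, and adjusted p = 0.769 with an estimated correlation). Another split of the libraries within runs put this list lower at a camera p of 1.02e-16 with the preset correlation, against 0.00114 in the real one. Ifit2 had -0.78 ± 0.21, Mx1 -0.66 ± 0.23, Iigp1 -0.47 ± 0.17 and Oasl1 -0.60 ± 0.26, while without Rosa26-edited 3 Mx1 had -0.39 and Oasl1 -0.30. The median was -0.37 within r770 but 0.17 within r595, and the call was lost without WRE-edited 2 or Rosa26-edited 2 or 3 in turn (adjusted p 0.144, 0.0610 and 0.147). Genes of p53 and DNA damage had a median of -0.05, with Plk2 at -0.54 ± 0.17, Pmaip1 at -0.76 ± 0.32 (-0.47 without WRE-edited 6), Btg2 at -1.24 ± 0.57 and Trp53inp1 at -0.52 ± 0.29 (-0.34 without WRE-edited 3). Without Rosa26-edited 1, which had 191 CPM, Btg2 was at -0.26. Endoplasmic reticulum stress genes had a median of -0.04, and the asparagine synthetase gene Asns (1.55 ± 0.41) was higher adjusted over the list alone (adjusted p = 0.0380) and by DESeq2, but the list-alone call was lost in 16 of 26 alternatives, 8 of them without 1 library. Dnajb9 had -0.47 ± 0.20, Trib3 0.64 ± 0.38 (0.30 without WRE-edited 6) and Manf -0.25 ± 0.19. Immediate early genes of tissue dissociation had a median of -0.37 and no call (adjusted p = 0.403), but passed lower in 4 of 25 alternatives, with Fos at -1.06 ± 0.67, Nr4a1 at -0.73 ± 0.50, Zfp36 at -0.45 ± 0.41 and Ier2 at -0.64 ± 0.61. Without Rosa26-edited 1, Fos was at -0.28, Nr4a1 at -0.11 and Ier2 at 0.36. Acute phase genes had a median of -0.06 (0.20 within r770 and -0.66 within r595) and passed lower in 1 of 25 alternatives, with Hp at -0.39 ± 0.30, Orm1 at -0.24 ± 0.23, Orm2 at -0.54 ± 0.65 (-0.06 without WRE-edited 6, -1.21 without WRE-edited 2) and Il1rn at 0.30 ± 0.37. Of the oncofetal list 5 genes were measured, with a median of 0.10, and the chromatin protein gene Hmga1 (0.71 ± 0.20) was higher adjusted over the list alone (adjusted p = 0.0192), which was lost in 12 of 26 alternatives, 4 of them without 1 library (0.41 without WRE-edited 6), next to Cd24a (-0.84 ± 0.52, and -0.38 without Rosa26-edited 2), Igf2bp2 (0.61 ± 0.42, and 0.31 without WRE-edited 3) and Sox4 (-0.51 ± 0.64, and -0.30 without Rosa26-edited 5). Imprinted genes outside the locus had a median of -0.02 against a mean of 0.00 and an upward test (adjusted p = 0.949), with Gnas at 0.31 ± 0.13, Mest at -0.39 ± 0.27, Slc22a3 at -0.30 ± 0.20 and Peg10 at 0.46 ± 0.35.

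Markers of cells other than hepatocytes were tested as 7 lists, of which 2 passed with the preset correlation of camera and none with an estimated correlation. All 11 stellate cell and fibroblast markers were negative, with a median of -0.62 (camera adjusted p = 8.51e-05, and adjusted p = 0.683 with an estimated correlation), including Des (-1.34 ± 0.47), Lum (-0.996 ± 0.401), Col1a2 (-1.10 ± 0.46) and Dcn (-0.62 ± 0.29). Col1a2 had -0.67 without WRE-edited 6 and Dcn -0.41 without Rosa26-edited 2, and the stellate call was lost without WRE-edited 3 and 6 together. The stellate medians were -0.47 within r770 and -0.81 within r595. All 13 macrophage markers were negative, with a median of -0.42 (adjusted p = 0.0368, and adjusted p = 0.769 with an estimated correlation), including Ctss (-0.57 ± 0.28), Adgre1 (-0.59 ± 0.31), Clec4f (-0.44 ± 0.23) and Timd4 (-0.61 ± 0.35). Without Rosa26-edited 2, Ctss had -0.27 and Adgre1 -0.32, and without Rosa26-edited 5 Timd4 had -0.28. The macrophage medians were -0.23 within r770 and -0.65 within r595. The macrophage call was lost in 9 of 25 alternatives, among them without WRE-edited 3 or 6 or Rosa26-edited 2 or 5 in turn (adjusted p 0.0647, 0.225, 0.502 and 0.388). Endothelial markers had a median of -0.22 and no call (adjusted p = 0.159), but passed lower in 2 of 25 alternatives, with Ehd3 at -0.26 ± 0.17, Cdh5 at -0.24 ± 0.19, Fcgr2b at -0.18 ± 0.15 and Clec4g at -0.26 ± 0.21. Neutrophil markers had a median of -0.69 with 5 measured (S100a8 -1.07 ± 0.57, Cxcr2 -1.51 ± 0.85, S100a9 -0.69 ± 0.48, Csf3r -0.34 ± 0.34), and lymphocyte markers -0.42 with 4 measured (Cd79b -1.16 ± 0.66, Gzma -0.40 ± 0.48, Nkg7 -0.43 ± 0.60, Ccl5 -0.18 ± 0.43). Without Rosa26-edited 2, S100a8 was at -0.11, S100a9 at 0.26, Cxcr2 at -0.96 (-2.66 without WRE-edited 2) and Cd79b at -0.63. The neutrophil list passed lower without Rosa26-edited 1 and higher without WRE-edited 6 and Rosa26-edited 2 and 5. Both kinds of marker were near the floor, with a mean log2 CPM of -0.05 against 0.36 for neutrophil and -0.97 against -0.61 for lymphocyte markers. Cholangiocyte markers had a median of 0.05 against a mean of 0.00 with the opposite sign, and ranged from Spp1 (-1.02 ± 0.51, and -0.63 without Rosa26-edited 2) through Bicc1 (-0.13 ± 0.45) to Sox9 (0.92 ± 0.34). The erythroid list had no call (adjusted p = 0.0712) but passed lower in 6 of 24 alternatives. Its members Hba-a1 (-2.44 ± 0.71), Hbb-bs (-1.66 ± 0.48), Hba-a2 (-1.83 ± 0.64) and Alas2 (0.45 ± 0.19) passed adjusted over the list alone. The globin genes were near the floor. Hba-a1 averaged 0.519 CPM against 1.97 (0 in WRE-edited 6), Hbb-bs 1.41 against 4.26 and Hba-a2 0.756 against 2.35. The globin values rest in part on Rosa26-edited 2. Without it Hba-a1 had -1.63, Hbb-bs -0.81 and Hba-a2 -0.77, and Hba-a1 and Hba-a2 no longer passed over the list alone. Alas2 was lost in 12 of 26 alternatives. Hba-a1 and Hba-a2 are near-identical copies, so their separate counts are uncertain.

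**Figure D3:**
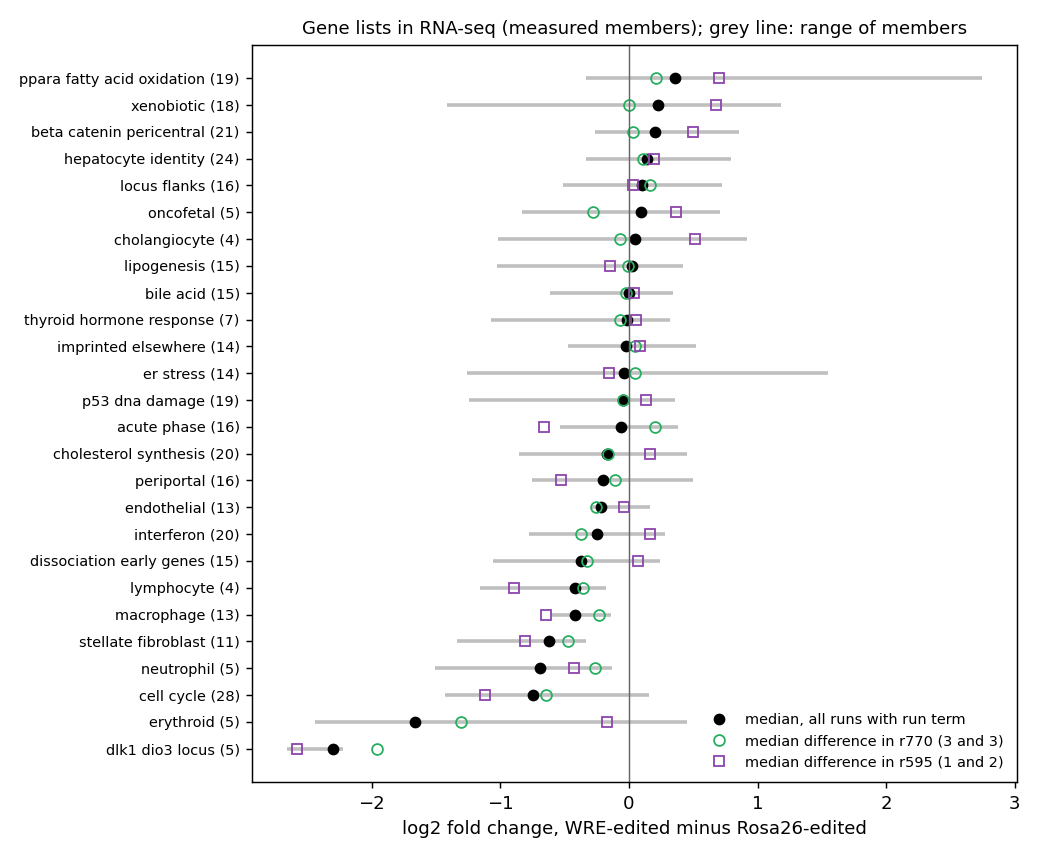
Log2 fold change (WRE-edited minus Rosa26-edited) of the 26 RNA-seq gene lists, with the median of the measured members over all runs, the medians within r770 and r595, and grey lines for the range of members. The DLK1/DIO3 locus lies lowest among lists that passed, at -2.30, followed by cell cycle at -0.75.

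The miRNA-seq comparison asked whether the microRNAs of the locus followed its transcripts. Of 51 measured locus miRNAs, 48 had negative fold changes, with a median of -0.88 (1.85-fold). The miRNA miR-127-3p, the most abundant of the 10 named here, was at 947 ± 36.7 CPM (SD, n = 3) in WRE-edited hepatocytes against 2250 ± 751 (SD, n = 3), a log2 fold change of -1.25 ± 0.28 (SE). Similar values were found for miR-337-5p (-1.26 ± 0.27), miR-154-5p (-1.29 ± 0.31), miR-299a-3p (-1.36 ± 0.35), miR-496a-3p (-1.29 ± 0.34) and miR-543-3p (-1.41 ± 0.38). Smaller ones were found for miR-134-5p (-1.08 ± 0.25), miR-409-3p (-1.05 ± 0.27), miR-434-3p (-0.94 ± 0.25) and miR-299a-5p (-0.88 ± 0.27). Together the locus miRNAs took 0.530% ± 0.0702 (SD, n = 3) of all counts in WRE-edited against 0.950% ± 0.399 (SD, n = 3) in Rosa26-edited libraries, an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Their share was 1.41% in Rosa26-edited 1 (95% exact binomial interval 1.39% to 1.43%). It was 0.716% and 0.724% in the other Rosa26-edited libraries and 0.4495% to 0.5741% in the WRE-edited libraries.

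Over all 355 miRNAs tested edgeR called 0, with 7 higher and 32 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.168, and DESeq2 called 4, all of them lower locus miRNAs. All 32 lower ones lay in the locus. Adjusted over the list alone, 25 locus miRNAs were lower (smallest adjusted p = 0.0241). The set was lower with the preset correlation (adjusted p = 3.33e-31) and had adjusted p = 0.0959 with an estimated correlation. In 27 of the 51 (52.9%) every WRE-edited library lay below every Rosa26-edited one, against 5% by chance and 11 of 304 outside the locus. The number adjusted over the list alone was 0 without WRE-edited 1, 2 or 3 in turn, 6 without Rosa26-edited 1 and 17 without Rosa26-edited 2. Near-identical miRNAs (miR-299a and miR-299b, the miR-376 family) and overlapping hairpins (miR-3071 and miR-136) could share reads, so their separate values are uncertain.

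**Figure D4:**
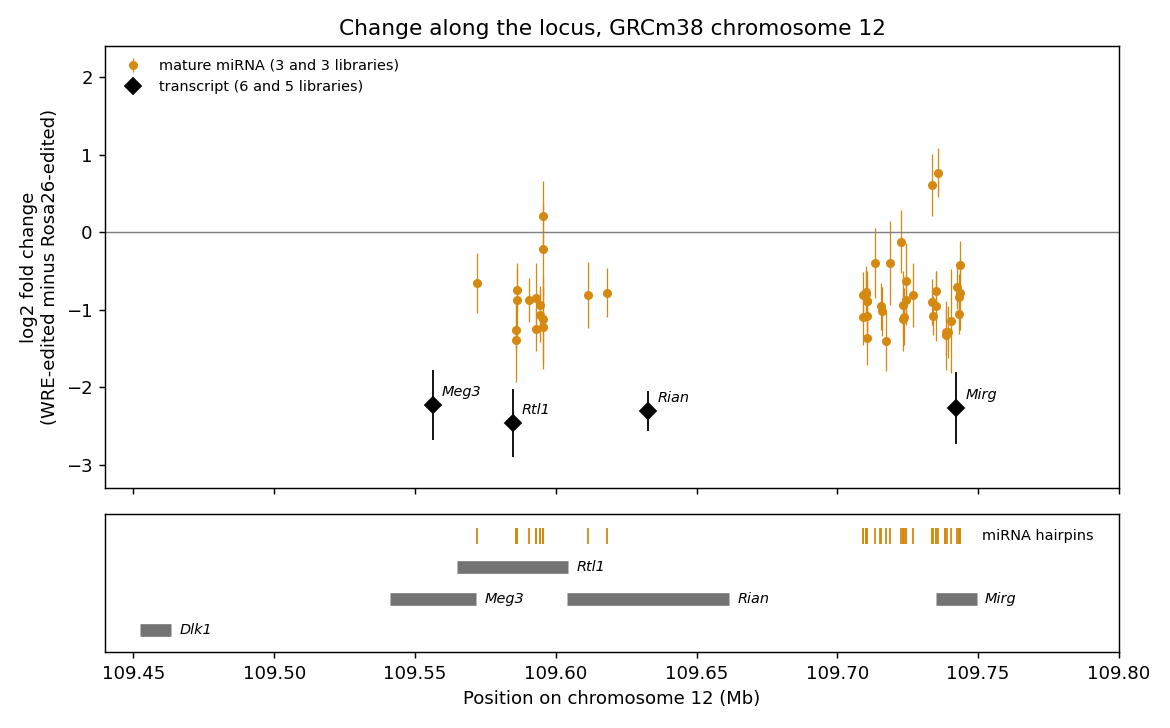
Log2 fold change (WRE-edited minus Rosa26-edited, with SE bars) of mature locus miRNAs and locus transcripts by position on chromosome 12 of GRCm38 in Mb, above a map of the annotated genes. Hairpins lie between 109571990 and 109743496, and 48 of 51 miRNAs lie below 0, with a median of -0.88 against -2.30 for the transcripts.

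Outside the locus the 304 tested miRNAs had a median of 0.05, with 6 higher and 0 lower at an unadjusted p under 0.05 and 0 past the threshold in edgeR or DESeq2. Mesenchymal and endothelial miRNAs were higher, with 7 of 8 positive and a median of 0.53 (camera adjusted p = 0.00112, and adjusted p = 0.430 with an estimated correlation). In this list miR-143-3p had 0.58 ± 0.23, miR-126a-3p 0.55 ± 0.24, miR-126a-5p 0.50 ± 0.25 and miR-199a-5p 0.60 ± 0.32, and its call was lost without Rosa26-edited 2 (adjusted p = 0.0513). Liver miRNAs had a median of -0.08, with miR-122-5p, the main hepatocyte miRNA, at -0.25 ± 0.23. The miR-17-92 family had 0.04, miR-200 family 0.31 and blood cell miRNAs 0.06, none of them called. The miR-200 list passed higher without Rosa26-edited 1 (median 0.81, camera adjusted p = 0.0236), and its median ranged from -0.11 to 0.81 over alternatives. In the p53 list only miR-34a-5p was measured, at -0.38 ± 0.21.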

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

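For each named gene, a library was singled out where it stood apart from the rest of its group by more than Dixon's 95% critical value; 11 of 208 groups did so, against 10 by chance (1 in 20). The tests by pairs of libraries within a run, without WRE-edited 3 and 6 and over all lists outside the locus, and the marker score covariate as a setting, were chosen after the result was seen.

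In blood and immune genes, Rosa26-edited 2 was highest for the globin genes Hbb-bs (11.7 CPM against 2.11 to 2.59) and Hba-a2 (7.35 against 0.808 to 1.28). Rosa26-edited 5 was highest for the acute phase gene Orm1 (952 CPM against 496 to 599). WRE-edited 5 was highest for the B cell gene Cd79b (1.25 CPM against 0.132 to 0.333), and WRE-edited 6 was lowest for the neutrophil gene S100a9 (1.75 against 2.75 to 3.15). Among hepatocyte and metabolic genes, Rosa26-edited 1 was lowest for Hpd (573 CPM against 703 to 736). WRE-edited 3 was lowest for Hsd17b13 (74.1 CPM against 115 to 143), and WRE-edited 1 was lowest for Cyp4a14 (11.3 CPM against 115 to 166), within the Rosa26-edited range. WRE-edited 3 was lowest for the stellate cell gene Des (0.140 CPM against 0.293 to 0.405), and Rosa26-edited 1 was highest for Btg2 (191 against 21.8 to 33.4). For Meg3, WRE-edited 4 was highest at 83.9 CPM against 42.7 to 51.8.

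The locus transcripts were lower by a median of -2.30. Only 1 of the 60 splits, the real one, gave a median as far from 0 (highest other 2.10). This makes chance unlikely without excluding it, since 1 of 60 is the smallest share that the splits allow. A difference between runs does not account for it, since in 11 of 11 pairs of libraries from the same run the WRE-edited one had the lower locus score. Fewer non-hepatocyte cells, as far as the marker score captures them, do not account for it either, since with the score as a covariate the locus median was -2.58. Stellate markers went from -0.62 to -0.09 and macrophage markers from -0.42 to 0.10, in part by construction, since the score is built from them. The stellate list still passed lower with the covariate, so the score need not capture the whole difference in cells. With the covariate Rian had -2.38 and adjusted p = 0.0605 (alternatives ranged from 9.40e-37 to 0.998), so the fold held while the over-all-genes call ended with 1 more term to estimate. Loss of β-catenin binding at the edited site may lower the measured transcripts of the locus list. This is a hypothesis that was not tested, since the edit itself and β-catenin binding were not analysed here.

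Cell cycle genes were lower by a median of -0.75. Only 1 of the 60 splits, the real one, gave a median as far from 0 (highest other -0.59). This makes chance unlikely only for a list named beforehand, while this one was picked out of 26 after the results were seen. Taking the smallest camera p of the 25 lists outside the locus in each split, 1 of 60 reached the real 2.57e-18, but another reached 1.02e-16, and the list had adjusted p = 0.180 with an estimated correlation, so the case for it stays open. In 11 of 11 pairs of libraries from the same run the WRE-edited library had the lower score, which argues against the run as the whole cause. Without WRE-edited 3 and 6 the median was -0.51, which argues against those libraries as its whole cause. That value rests on r770 alone, and members passing adjusted over the list alone fell from 18 to 5. With the marker score as a covariate the median was -0.61 and this number 9. Stellate markers still passed lower there, so this argues against fewer non-hepatocyte cells as the whole cause only as far as the score captures them. With length offsets the median was -0.45, and with WRE-edited 4 and 6 summed and no run term -0.32. Differences between animals in the time since tamoxifen or in the yield of isolation were not tested and stay open, and the r711 libraries without a control reached 2.77.

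Locus miRNAs were lower by less than the transcripts (-0.88 against -2.30). Scaling pulled by the locus miRNAs does not account for this, since factors computed without them gave -0.90. Over the miRNA libraries whose group and name number also occur in RNA-seq run r595 (1 WRE-edited and 2 Rosa26-edited) the miRNA median was -0.86, but with 3 libraries a difference of animals cannot be told apart from a difference between the assays. Moreover 1 name number belongs to a WRE-edited library in miRNA-seq and to a Rosa26-edited library in RNA-seq, so the numbers need not mark animals. Slow turnover of mature miRNAs might also leave them less reduced, which was not tested.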

How the results depend on the processing

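The alternatives added after seeing the data were length offsets, leaving out mitochondrial and 7S RNA, leaving out WRE-edited 6 with Rosa26-edited 2 and 5, leaving out WRE-edited 3 and 6, and the marker covariate. The locus median stayed between -2.58 and -1.95 and 4 to 5 locus genes were lower adjusted over the list alone in all of the alternatives, and the cell cycle median between -0.86 and -0.24. Length offsets moved the cell cycle median from -0.75 to -0.45 and its number adjusted over the list alone from 18 to 10.

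Against 1 gene and 1 locus gene in edgeR, DESeq2 Wald tests gave 83 genes and 5 locus genes. No filter gave 450 and 5, where the prior degrees of freedom became infinite against 5.6, so the spread of single genes was ignored. The count was 0 genes and 0 locus genes without the run term, with r770 only and without the r711 libraries, the last 2 of which use fewer libraries; Rian had adjusted p of 0.0755, 0.172 and 0.0527. With WRE-edited 4 and 6 summed and no run term Rian alone passed (-1.97, adjusted p = 0.0461), 9 lists passed, and cell cycle had -0.32 and 0 members adjusted over the list alone. Leaving out 1 library gave 0 to 2 genes (2 without Rosa26-edited 3), 0 to 1 locus genes and 6 to 11 lists (7 with all, 11 without Rosa26-edited 1). Without WRE-edited 3 and 6 there were 0 genes, 0 locus genes and 4 lists, and without WRE-edited 6 and Rosa26-edited 2 and 5 there were 11 lists and 1 gene, Meg3. With the marker covariate 0 locus genes passed, and 1 gene, a higher one. Without WRE-edited 6 and Rosa26-edited 2 and 5 neutrophil markers turned from -0.69 to 0.64 and passed higher (adjusted p = 0.0334, in a range over alternatives up to 0.924), lipogenesis passed lower at -0.13, and macrophage markers reversed to 0.075 (adjusted p = 0.116); macrophage markers also reversed to 0.10 (adjusted p = 0.12) with the covariate, which is built partly from them. The cause of the other changes was not tested. Among single values of named genes 2556 kept their sign and their side of the threshold. With the sign kept, 50 passed it and 13 lost it, and 57 changed sign without a call in the main fit. Among RNA-seq and miRNA lists 549 kept both the sign of the median and the side. With the sign kept, 40 passed and 18 lost it. A further 90 changed sign without a call in the main fit, among them the lipogenesis and neutrophil calls above, and 2 called ones changed sign.

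Residuals of the 5 same-numbered RNA-seq pairs correlated at -0.11, -0.41, -0.02, 0.12 and 0.15, and those of the 3 miRNA pairs at 0.20, -0.28 and 0.04. With only the group means removed, the RNA-seq pairs correlated at 0.129, -0.09, 0.178, 0.013 and -0.075. The mixed signs give no sign of pairing by replicate number. They cannot rule it out, since residuals of WRE-edited 4 and 5, the only r711 libraries, mirror each other. A replicate block with the run term gave 2 genes, the 2 locus genes Mirg and Rian, and without the run term 1 gene, Mirg. In miRNA-seq the block gave 0 miRNAs and 21 adjusted over the list alone.

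For miRNAs, DESeq2 Wald tests gave 4 miRNAs and 4 locus miRNAs against 0 in edgeR. Of the 25 adjusted over the list alone, library totals gave 0, and leaving out 1 library 0 to 34. Library totals moved the median of all miRNAs to 0.14 from -0.01, and the locus median was -0.76 there and -0.997 to -0.590 over all alternatives. Dlk1, Dio3 and Dio3os were removed by the filter and had -0.05, 1.15 and -0.04 without it, none of them called.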

Other observations

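All genes and miRNAs singled out in this part were chosen after their values were seen, while the tests of splits, position and arms were written before.

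Some genes outside the fixed lists were picked for a small p. Racgap1, a regulator of cytokinesis, had a log2 fold change of -1.04 ± 0.17 (SE), the kinetochore gene Nuf2 -1.52 ± 0.28, the spindle gene Hmmr -1.32 ± 0.27, the mitotic kinase gene Melk -1.59 ± 0.32 and Cip2a -1.38 ± 0.27, each negative within r770 and within r595 (edgeR adjusted p 0.213 to 0.235, n = 6 and 5). In the other direction the transcription factor gene Atoh8 had 1.31 ± 0.23 (adjusted p = 0.213). The mitochondrial carrier gene Slc25a30 was at 81.7 ± 28.7 CPM (SD, n = 6) against 27.7 ± 16.9 (SD, n = 5), a log2 fold change of 1.36 ± 0.28 (adjusted p = 0.263). None of these passed over all genes.

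The non-coding transcripts Gm26945 (-2.75 ± 0.55) and Gm27000 (-2.72 ± 0.60) had fold changes as large as those of the locus transcripts (adjusted p = 0.235 and 0.281), but have no coordinates in the table used here. Gm34667, between Mirg and Dio3 at 109992758 to 110023992, went the other way (1.32 ± 0.51, adjusted p = 0.441) at 0.691 ± 0.298 CPM against 0.270 ± 0.127. Within the miRNA cluster the exceptions were miR-453 (0.77 ± 0.32), miR-382-3p (0.61 ± 0.40) and miR-3071-5p (0.21 ± 0.45), while the other arm of the miR-382 hairpin, miR-382-5p, had -0.90 ± 0.29. WRE-edited 4 and 6, whose names carry the same number, differed in cell cycle score (2.48 in r711 against 1.52 in r595).

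The fall of a locus miRNA might depend on its position along the cluster, but Spearman's rho of the log2 fold change and the hairpin start was 0.0179 over 35 hairpins (Pearson's r 0.0686; permutation p = 0.918), across miRNAs that are not independent replicates. Both arms of a hairpin could share the size of the fall: Spearman's rho of the arms was 0.5 over 16 hairpins (Pearson's r 0.45; permutation p = 0.0514), which leaves this open.

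Of the 60 splits of the RNA-seq libraries within runs, 4 gave at least as many genes as the real 1 (highest other 2), and 39 gave at least as many lists as the real 7 with the preset correlation (highest other 14), so chance cannot be excluded for either count. In miRNA-seq all 10 of 10 splits gave as many miRNAs as the real 0 (highest other 0), and 1 of 10 gave a locus median as far from 0 as the real -0.88 (highest other 0.64), and 10 splits are too few for a share under 0.05.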
